A study of Mus musculus with 6 samples.

How the data were processed

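Total RNA from intestinal epithelial cell preparations of 6 mice was measured on Affymetrix arrays, with 1 array per mouse. The mice were of a mixed strain background. All carried a floxed Pggt1b gene, which encodes the beta subunit of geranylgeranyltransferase type I (GGTase-I). The 3 control mice lacked the Villin-CreERT2 transgene, a tamoxifen-inducible recombinase driven by an epithelial promoter, and the 3 deficient mice carried it. Per the labels' protocols, all mice received 1 mg tamoxifen on each of 3 successive days and cells were isolated on day 6 after the start of treatment. The part of the intestine that was sampled, the sex and age of the mice and the scan batch are not given in the sources used here, so no batch could be tested.

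The deposited values are log2 expression values, 1 per probe set and array, made by the authors. The submitters' processing notes name Partek 6.5 and GCRMA, a background correction and normalization that uses probe sequence, without saying in which step each was used. The log2 scale was inferred from the values, which ran from 0.42 to 16.4 with medians between 3.26 and 3.33 per array. GCRMA gathers unexpressed probe sets near a low floor, and changes measured against that floor depend on the background model. No detection calls were used here, and the number of arrays limits the precision. No scanner intensities were analysed here.

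The table held 45101 probe sets. The 64 control probe sets were left out. A platform annotation gave 1 gene symbol for 34958 probe sets, several for 932 and none for 9211. Of those with 1 symbol, 34754 matched an Entrez ID of the gene table of assembly GRCm38.p6, which changed 0 symbols. No coordinates are printed because the build of the platform annotation was not named. Each of 18194 genes was represented by the probe set with the highest mean over all 6 arrays. Genes above 5 (log2) on at least 3 arrays were tested, which left 8893. Where a gene lay at or below 5 on all 3 arrays of a group, the fold change is also given as "at least", computed as the mean of the brighter group against the level 5. Where some arrays of a group lay there, for called genes with a fold in the text, values at or below 5 were raised to 5 before the fold was taken, which is then also given as "at least". That level is the filter used here, not a measured background. The probe sets used for Slc2a3, Cd160, Muc4, Srf, Pkp2, Rrm2, Vim, Slc51a, Srxn1, Cubn, Dbp and the T cell receptor segments include designs that can match several transcripts, so related genes may contribute to their values.

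Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 changes are deficient minus control. Errors of group means are SDs over 3 mice, and errors of log2 changes are standard errors of the fit. A test was run on simulated arrays of 8893 genes, with the means of this comparison and its spreads shuffled among genes. In it 30.0% of 50 genes changed by 1 on the log2 scale were called, 76.0% of 100 changed by 2 and 92.0% of 50 changed by 3. In that simulation 12 of 149 calls were false. For the set test, 6 of 200 unchanged simulated lists had a p under 0.05. Genes were drawn independently in both simulations. They therefore cannot show how correlation among list members affects the set test.

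Gene lists were fixed before the data were examined. There were 31 lists with 610 entries, of which 553 were on the array under a single symbol and 4 were renamed through synonyms. Lists with at least 3 tested members, 30 in all, were tested with camera at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the lists. The red blood cell list had too few tested members. The results of 2 tested lists and of members named through them are not reported here, although the counts over all genes and lists include them. Camera was repeated with the correlation estimated per list, and fry was run as a further set test. Members past the threshold were counted over all genes and adjusted over the list alone.

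The rule for named genes, also fixed before the data were examined, took Pggt1b, the 10 largest rises and 10 largest falls by fitted change among called genes whose groups did not overlap, and up to 4 called members per list. For a list with no called member, up to 2 members with the smallest p are given as values only. Other genes are marked in the text as chosen after their values were seen.

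Alternatives changed the variance moderation, array weights, filter, normalization, handling of probe sets, set test and replicate block, and left out each array in turn. Permutation tests of single values between 3 and 3 arrays cannot give a two-sided p below 0.10.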

Results

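Expression was measured on 1 array per mouse in preparations of intestinal epithelial cells, taken from 3 controls and from 3 animals in which Pggt1b was floxed and an inducible epithelial recombinase was present. The comparison addresses how loss of GGTase-I, an enzyme that attaches geranylgeranyl lipids to proteins, changes expression in these cells by day 6 after the start of tamoxifen. The deficient mice alone carried the recombinase, so its own effect and that of the deletion are not separated by this design. The arrays were alike in range: between 35.6% and 36.5% of the 45101 probe sets lay above 5 (log2) on each array. Over the 8893 genes tested, correlations between arrays of one group ran from 0.953 to 0.980. Those between groups ran from 0.903 to 0.969. The highest came from deficient replicate 3, at 0.952 to 0.969 with controls against 0.953 to 0.979 with its own group.

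The deleted gene did not separate the groups at the RNA level. The Pggt1b probe set used here read 9.39 ± 0.14 (SD, n = 3) in controls and 9.16 ± 0.52 (SD, n = 3) in the arrays labelled deficient, a log2 change of -0.24 ± 0.27 (SE) with a limma adjusted p of 0.678. Deficient replicate 1 had the highest of the 6 values, 9.75, while deficient replicates 2 and 3 lay below all controls at 8.88 and 8.83. The change was -0.54 without deficient replicate 1, -0.10 and -0.07 without deficient replicates 2 and 3, and -0.16 without control replicate 2, with adjusted p from 0.267 to 0.913 over the fits that left out 1 array. The other probe sets of the gene changed by 0.15, -0.08 and 0.01 on the log2 scale. Where these probe sets lie relative to the deleted part of the gene is not given in the sources used here, and a probe outside it would not report the deletion. The values therefore neither check nor contradict the labels, and every direction below rests on the labels alone.

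Far more genes were lower than higher in the arrays labelled deficient. Genes of lymphocytes were among the falls with the largest fitted changes, and the rise with the largest fitted change was that of Anxa10. Of 8893 genes, 186 passed the threshold, 176 lower and 10 higher in the deficient arrays, and 179 of them changed at least 2-fold. The fixed gene lists held 25 of them, 17 being lower genes of the leukocyte lists, while 151 lower and all 10 higher genes lay outside every list. The 17 do not count every leukocyte gene among the lower calls, since Cd244a, Cd160 and T cell receptor segments lay outside the lists. So did Cd69, Cd96, Fasl, Ctsw, Ikzf1, Ikzf3, Lat, Lcp2, Sash3, Xcl1 and others, named here after their values were seen. How many of the 151 are leukocyte genes was not counted. The median log2 change was -2.35 among the lower genes and 2.21 among the higher genes, or -1.73 and 1.88 with genes near the floor set at their bound. All 186 had non-overlapping groups, which with 3 arrays per group nearly follows from passing the threshold. So did 25.7% of the genes tested, where chance gives 10% for a single gene. Genes are not independent of each other, so this share is no test. The median change of all genes tested was -0.04. Leaving out control replicate 1, control replicate 3 or deficient replicate 2 reduced the total to 93, 104 or 101, and the lower genes to 88, 101 or 97. Higher calls fell to 3 to 5 when any array except deficient replicate 3 was left out, and reached 36 without that array.

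The 10 higher genes were led by Anxa10, an annexin, which stood near the floor in controls at 2.54 ± 0.27 (SD, n = 3) and reached 10.6 ± 1.87 (SD, n = 3) in the deficient arrays. This is at least 47.6-fold against the level 5 (fitted log2 change 8.03 ± 0.84, limma adjusted p = 0.0046). Ly6d, a Ly6 family surface protein, also stood near the floor in controls and was at least 2.38-fold higher (limma adjusted p = 0.028). Capg, an actin filament capping protein, rose 10.4-fold (log2 3.38 ± 0.43, adjusted p = 0.011). Pgap1, which remodels GPI anchors, rose 5.15-fold. Gch1, the first enzyme of tetrahydrobiopterin synthesis, rose 5.03-fold, and the membrane mucin Muc4 rose 4.24-fold. Smaller rises were those of the myosin light chain Myl7 (3.18-fold), the transcription factor Klf7 (3.04-fold), 2210407C18Rik (3.02-fold) and the palmitoyltransferase Zdhhc2 (2.24-fold), with limma adjusted p between 0.0176 and 0.0424 for the genes from Pgap1 on. Of the 10, Anxa10 alone passed in all 6 fits that left out 1 array. The others failed in at least 2 of these fits, with adjusted p up to 0.194 (Gch1, which passed in 1 as did Myl7 and Zdhhc2), although none of these log2 changes moved by over 1.5 times.

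**Figure D1:**
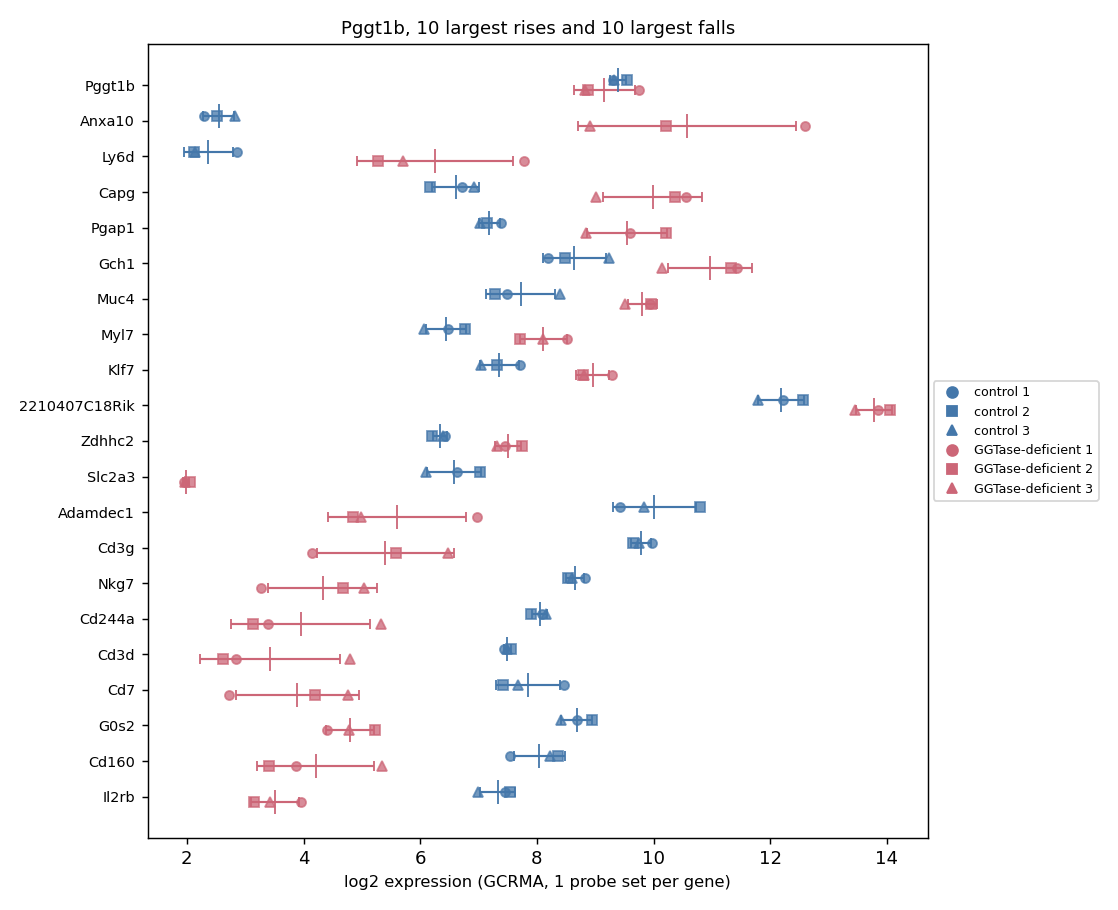
Log2 expression of Pggt1b and of the 10 rises and 10 falls with the largest fitted changes (x axis, GCRMA log2 values) on each array, with points for arrays and the group mean and SD (n = 3). Pggt1b overlaps between groups and the other genes do not, with Anxa10 at a mean of 2.54 in controls and 10.6 in the deficient arrays.

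Among the 10 falls with the largest fitted changes were genes of T cells and natural killer-like lymphocytes. All 10 reached the level 5 or lay below it on at least 1 deficient array, so their folds are given as bounds and their order is not settled. Cd3g and Cd3d, subunits of the T cell receptor complex, fell at least 17.2-fold and at least 5.62-fold (fitted log2 -4.39 ± 0.54 and -4.07 ± 0.55, limma adjusted p = 0.0089 and 0.012). Nkg7, a cytotoxic granule protein, fell at least 12.5-fold. The lymphocyte receptors Cd244a and Cd160 fell at least 7.66-fold and 7.61-fold. Cd7 fell at least 7.21-fold and Il2rb, a subunit of the interleukin-2 and interleukin-15 receptors, at least 5.01-fold. Outside this group, Slc2a3, a glucose transporter, fell at least 3.00-fold and read about 2 on all 3 deficient arrays. Adamdec1, a metalloprotease, fell at least 20.5-fold and G0s2, an inhibitor of triglyceride breakdown, at least 12.2-fold. Cd3g lay above 5 on 2 deficient arrays, Nkg7, Cd244a, Cd160, Adamdec1 and G0s2 on 1, and Cd3d, Cd7, Il2rb and Slc2a3 on 0. Limma adjusted p for these 10 genes lay between 0.00108 and 0.0154. Nkg7, Il2rb, Slc2a3 and G0s2 passed in all 6 fits that left out 1 array. The other 6 failed in at least 2 of them, each without control replicate 3, with adjusted p up to 0.0723 (Adamdec1).

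Of the 30 fixed lists tested with camera, 7 passed at the preset correlation, 3 higher and 4 lower, and 0 with an estimated correlation (1 at an unadjusted p under 0.05). The list of T cell and intraepithelial lymphocyte markers fell as a group. All 15 measured members had lower means in the deficient arrays and 13 passed over all genes (15 adjusted over the list alone), with a median log2 change of -3.07, or -2.82 with the 3 members near the floor set at their bound. Mean levels of the list, relative to its control mean, were 0.07, -0.00 and -0.07 in the controls and -3.87, -3.14 and -2.55 in deficient replicates 1, 2 and 3. The members that did not pass over all genes were Gzma and Cd3e, at -2.99 and -1.51 (limma adjusted p = 0.051 and 0.081). Cd3e is a subunit of the T cell receptor complex, as are Cd3g and Cd3d, and fell less than these. Gzma and Cd3e are named here after their values were seen. Il2rb and Nkg7 are given above. Coro1a, a leukocyte actin regulator, fell 7.08-fold and Ptprc, the pan-leukocyte marker CD45, 6.27-fold. Ccl5, a chemokine also held by the inflammatory list, fell 8.99-fold, but failed without any 1 control or without deficient replicate 2 (limma adjusted p up to 0.1003). Camera with the preset correlation gave an adjusted p of 2.53e-18, while with an estimated correlation the adjusted p was 0.556. Fry gave an adjusted p of 0.0167 for movement in one direction.

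The myeloid list, of markers of another cell type that such preparations can hold, and the MHC class II list, a pathway list, passed camera in the lower direction at the preset correlation (adjusted p = 0.933 for both with an estimated correlation). In the myeloid list 4 of 13 members fell over all genes (5 adjusted over the list alone): Fcer1g (5.48-fold) and Tyrobp (7.71-fold), signalling adaptors that natural killer cells also use, the macrophage marker Adgre1 (3.89-fold) and the integrin Itgax (at least 2.15-fold). When 1 array was left out, Itgax passed in 1 of 6 fits (limma adjusted p up to 0.122, passing without control replicate 3), and Adgre1 failed without deficient replicate 2 (0.0531). Its median was -1.07 and its camera adjusted p 1.60e-04 (adjusted p = 0.933 with an estimated correlation). Without deficient replicate 3 the median was -0.69. Like the T cell list, this list stood lower in the deficient arrays, but the order of these arrays differed. Its mean levels were -1.24, -0.88 and -1.63 in deficient replicates 1, 2 and 3, so replicate 3 was lowest here and highest in the T cell list. The 5 members of the MHC class II list, genes of antigen presentation to T cells, had a median of -1.72. Of these 0 passed over all genes and 5 passed adjusted over the list alone (camera adjusted p = 0.0018, adjusted p = 0.933 with an estimated correlation). H2-Eb1 and H2-DMa changed by -1.75 and -2.21. The stromal, muscle and endothelial list had a median of -1.07 over 7 members, 0 past the threshold (4 adjusted over the list alone, camera adjusted p = 0.218), with Vim at -1.07 and Col1a2 at -1.69. In the B and plasma cell list, 0 of 4 members passed over all genes and 3 passed adjusted over the list alone, in both directions. Jchain was at -1.62 and Blnk at 1.31 (0.85 without deficient replicate 1), and the camera adjusted p was 0.770.

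**Figure D2:**
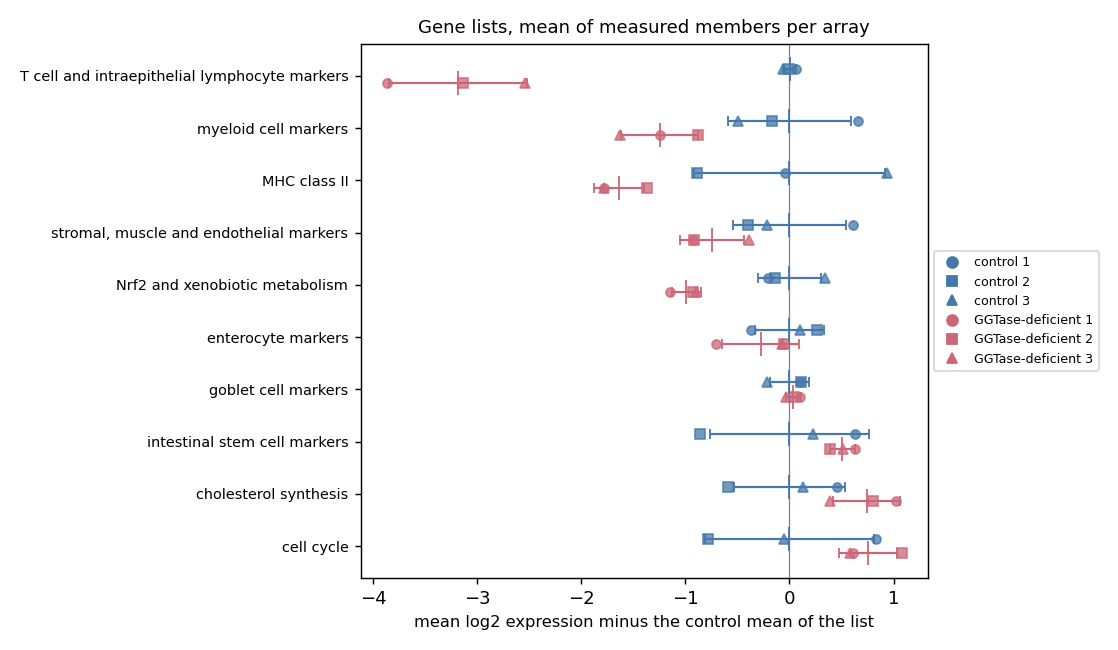
Mean log2 expression of the measured members of 10 gene lists on each array, relative to the control mean of the list (x axis), with points for arrays and the group mean and SD (n = 3). The T cell list lies between -3.87 and -2.55 in the deficient arrays, while control replicate 1 lies within the range of the deficient arrays for the cell cycle list, at 0.84, and the cholesterol list, at 0.46.

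In the Nrf2 and xenobiotic list, Ephx1, the microsomal epoxide hydrolase, was the 1 of 19 members that fell over all genes, by at least 9.35-fold with 2 deficient arrays above 5 (fitted log2 -3.25 ± 0.28, limma adjusted p = 0.0023). Adjusted over the list alone, 10 fell and 0 rose. By mean, 15 members were lower and 4 higher, among them Srxn1 at 0.63 and Gsta4 at 0.48. The list mean was -0.99 and the camera adjusted p 0.0018 (adjusted p = 0.933 with an estimated correlation). The enterocyte list had a median of -0.21 over 22 members, 0 of which passed by either adjustment and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.742). Lct, the brush border lactase, was at -0.94 and the glucose transporter Slc2a2 at -1.98. Without deficient replicate 1 these values were -0.51 and -0.96. In the list for lipid absorption and fatty acid oxidation, Ppara, a nuclear receptor for fatty acids, was the 1 of 26 members that fell, by 2.16-fold (limma adjusted p = 0.042, camera adjusted p = 0.119). Ppara did not pass in any fit that left out 1 array.

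The cell cycle and cholesterol synthesis lists passed camera in the higher direction at the preset correlation (adjusted p = 0.935 for both with an estimated correlation), without a single member past the threshold. In the cell cycle list 23 of 24 members had higher means in the deficient arrays, with a median of 0.75. Rrm2 was at 0.90 and Cdc6 at 0.81, and the camera adjusted p was 3.51e-06. In the cholesterol list 17 of 20 members had higher means, with a median of 0.77, Mvk at 1.55 and Cyp51 at 1.51. Its camera adjusted p was 4.22e-05. In both lists 0 members passed with limma over all genes or adjusted over the list alone, and 5 and 6 had an unadjusted p under 0.05. Both lists were lowest in control replicate 2, at -0.79 and -0.59 relative to their control means, as were the stem cell list at -0.86, the Paneth list at -0.58 and the ileum list at -1.51, while the proximal list stood at 0.75 and the tuft list at 1.35 in that array. Without it the medians were 0.34 and 0.54 and control replicate 1 still lay among the deficient arrays.

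Prenylation enzymes, the group that holds the deleted gene, did not pass as a list. Of 11 members, 0 passed with limma over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. Fdps, which makes the precursor of both prenyl lipids, was at 2.64 ± 1.04 (SE) with a limma adjusted p of 0.276, and Icmt was at -0.31. Without control replicate 2, which read 4.49 for Fdps, the Fdps change was 1.35. The list median was 0.01 and its camera adjusted p 0.742.

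In the actin cytoskeleton and SRF list, 3 of 24 members fell over all genes: the calponin Cnn2 (4.73-fold), the membrane-cytoskeleton linker Msn (4.62-fold) and the transcription factor Srf (3.23-fold), with limma adjusted p of 0.0098, 0.019 and 0.042. Cnn2 and Msn are also abundant in leukocytes, and they fell beside the T cell list. Srf did not pass in any fit that left out 1 array. Cnn2 failed without control replicate 1 or 3 and Msn without any 1 control (adjusted p up to 0.0576 and 0.0899). Adjusted over the list alone 4 fell and 1 rose, and camera gave an adjusted p of 0.956. In the junction list, 0 of 27 members passed by either adjustment. Its median was 0.19, with Pkp2 at 0.72 (0.44 without deficient replicate 1) and Tjp1 at 0.71, and its camera adjusted p of 0.026 (adjusted p = 0.935 with an estimated correlation) became 0.052 without control replicate 1 and 0.294 without deficient replicate 1. The median was 0.07 without deficient replicate 1 and 0.08 without control replicate 2, and the adjusted p ran from 0.00121 to 0.935 over all alternatives. At an unadjusted p under 0.05, 3 members were higher. In the YAP target list 0 of 10 members passed over all genes and 2 in each direction adjusted over the list alone, with Amotl2 at -1.16 and Tead1 at 1.41 (camera adjusted p = 0.521).

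Lists for cell death, stress and defence did not pass. Of 22 apoptosis and p53 target genes, 0 passed with limma and 4 had an unadjusted p under 0.05, with Xiap at 0.49 and Casp8 at 0.90 (camera adjusted p = 0.742). The probe sets of Xiap disagreed in direction, from -0.03 to 0.59. Of 22 unfolded protein and integrated stress genes, 0 passed over all genes and 1 rose adjusted over the list alone. Asns was at 1.17 and Edem1 at 0.37 (camera adjusted p = 0.218), and the 2 probe sets of Edem1 disagreed in direction, at -0.04 and 0.37. Of 19 inflammatory genes, Ccl5 was the 1 that fell, with the losses given above (camera adjusted p = 0.502). Of 14 antimicrobial genes 0 passed and 1 had an unadjusted p under 0.05, with Nlrp6 at -0.57 and Pigr at -0.57 (camera adjusted p = 0.742). Of 23 interferon response genes 0 passed and 1 had an unadjusted p under 0.05, with Psmb9 at -0.89 and Psmb8 at -1.06, or -0.54 and -0.50 without deficient replicate 1 (camera adjusted p = 0.742).

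Markers of the other epithelial cell types did not pass camera as lists. By fry in either direction, which asks whether members change at all, the goblet and Wnt lists passed (adjusted p = 0.00267 and 0.0154). In the goblet cell list 1 of 14 members fell: Gfi1, a transcription factor of secretory cells and of lymphocytes, by 2.51-fold (limma adjusted p = 0.0098, camera adjusted p = 0.521). Gfi1 failed without control replicate 1, control replicate 3 or deficient replicate 2 (adjusted p up to 0.0637). The stem cell list had a median of 0.47 over 10 members and the Wnt target list -0.27 over 8, with Rnf43 at -0.74 and Sox9 at 0.94 in both (camera adjusted p = 0.211 and 0.742). Rnf43 passed adjusted over each list alone. The Paneth list had a median of 0.44 over 5 members, with Mmp7 at 1.62 and Pla2g2a at 0.44 (camera adjusted p = 0.218). Mmp7 was at 0.55 without control replicate 2, and Pla2g2a at 0.05 without deficient replicate 2 and 0.73 without deficient replicate 1. The enteroendocrine list had a median of -0.32 over 16 members, with Pyy at 0.45 and Gcg at 0.93 (camera adjusted p = 0.959). The tuft cell list had a median of 0.13 over 5 members, with Alox5ap at -1.95 and Siglecf at -1.23 (camera adjusted p = 0.956). Medians of the regional lists were 0.01 for the proximal small intestine (Ckb 0.94, Cybrd1 3.21), 0.43 for the ileum (Slc51a -0.55, Fgf15 1.94) and 0.25 for the colon (Car4 0.63, Ceacam10 0.76), with camera adjusted p of 0.436, 0.609 and 0.521. When 1 array was left out Fgf15 ran from 0.80 (without control replicate 2) to 3.54 (without deficient replicate 3), and Slc51a from -0.81 (without deficient replicate 2) to -0.21 (without deficient replicate 1). Over the same fits Pyy ran from 0.25 to 0.60, Gcg from 0.40 to 1.25, Alox5ap from -2.63 to -1.23, Siglecf from -1.999 to -0.49, Car4 from 0.40 to 0.89 and Ceacam10 from 0.37 to 1.04. In the stem, Wnt, Paneth, enteroendocrine, tuft and regional lists 0 members passed with limma over all genes. At an unadjusted p under 0.05 there were 2 stem, 3 Wnt, 1 tuft and 3 proximal members and 0 in the Paneth, enteroendocrine, ileum and colon lists. In the proximal list 2 rose adjusted over the list alone.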

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

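The tests of explanations for the 3 patterns below were chosen after the values were seen; the count of other splits was not.

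Probe sets without a single gene symbol were left out of the main fit. When every probe set was fitted as its own feature, 23 of 1803 such probe sets passed the threshold, 21 lower and 2 higher in the deficient arrays than in the controls. Of all 16281 probe sets in that fit 234 passed, so those without a single symbol were called no more often than probe sets in general. The 2 higher ones lay at or below 5 on all 3 controls, with means of 3.80 and 4.28, and had means of 5.61 and 5.55 in the deficient arrays. Against the level 5 they were at least 1.53-fold and 1.46-fold higher (limma adjusted p = 0.023 and 0.017).

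The 186 genes past the threshold were set against other splits of the 6 arrays. Of the 10 splits into 3 and 3, 1 gave as many genes, the real one, and the highest of the others gave 0. With 10 splits the share cannot fall below 0.1.

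For the fall of lymphocyte transcripts, the first pattern, an array-wide scaling would move every list alike, but the enterocyte median lay 2.86 (log2) above that of the T cell list, outside the quartiles of the T cell members. The 5 stromal members with a control mean above 7 had a median of -1.30 and all lay above the upper quartile of the T cell list, -2.82. Dcn stood at 0.13, but Vim, Sparc, Col1a2 and Col3a1 stood at -1.07, -1.30, -1.69 and -1.74. Stromal transcripts therefore fell less than most T cell members. Members of the T cell list also fell unequally, with Cd3e at -1.51, so the comparison cannot exclude an equal loss of cells. A loss of non-epithelial cells, whether alike or different between cell types, stays open. Of the measured T cell members 100% lay under -1 on the log2 scale, but this restates the pattern and is no test of a smaller number of lymphocytes among the collected cells, which stays open. The abundant members Gzma, which did not pass, and Ccl5, the 1 measured member that another list holds, had means of 13.7 and 12.5 in controls and 10.7 and 9.30 in the deficient arrays. Whether fewer lymphocytes resided in the epithelium or fewer were recovered during isolation remains open, as does lower expression per cell, since no cell counts were analysed here and the labels name no sort.

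The second pattern is the higher cell cycle and cholesterol synthesis lists, which may rest on control replicate 2. Without it the lower of the 2 ratios to the original medians was 0.45, for the cell cycle, and 0.70 for cholesterol synthesis. Both lists still passed camera at the preset correlation, with adjusted p of 7.81e-04 and 5.21e-04 (over all alternatives 4.43e-13 to 0.935 and 1.19e-06 to 0.935). The stem cell list moved with the cell cycle list across controls 1 to 3 (0.63, -0.86 and 0.23 against 0.84, -0.79 and -0.05), as did the Paneth list (0.63, -0.58 and -0.05) and the ileum list (0.71, -1.51 and 0.80), while the proximal list moved the other way (-0.43, 0.75 and -0.32) and the tuft list stood at 1.35 in control replicate 2. In neither list of the pattern did all deficient arrays lie above both remaining controls, so a difference in the share of crypt cells or in the part of the intestine between single preparations and a difference between genotypes cannot be told apart.

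The third pattern is the lower xenobiotic metabolism list. A lower share of enterocytes would lower enterocyte markers alike, but their median was -0.21 with a lower quartile of -0.73, and the xenobiotic median lay below that quartile (list mean -0.99). Deficient replicates 2 and 3 stood at -0.05 and -0.07 for the enterocyte list and at -0.93 and -0.89 for the xenobiotic list. Deficient replicate 1 stood at -0.70 and -1.15, so a lower share of enterocytes stays open for that array. A change of these genes within enterocytes, by the deletion, the recombinase or another difference between the mice, stays open and was not tested.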

How the results depend on the processing

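Variance trend, trend with robust estimation and quantile normalization kept all gene counts within 1.5 times. The total of 186 became 293 with array weights, 85 without a filter, 99 with the level 7 and 117 with the mean of all probe sets. The 10 higher genes became 33, 0 and 6 with array weights, no filter and probe set means, and 17 with median centring, which moved the median change of all genes from -0.04 to 0.03. The 176 lower genes became 85, 90 and 111 with no filter, the level 7 and probe set means, and the 179 calls of at least 2-fold became 76, 96 and 113. The cause was not tested. Leaving out 1 array gave 93 to 239 genes, 3 to 36 higher, 88 to 203 lower and 93 to 239 of at least 2-fold. The highest values came without deficient replicate 3, where 151 of 239 calls were among the original 186. The replicate block gave 141 genes, 127 of them among the original calls. The labels do not say that a number marks a shared litter or day, deviations of same-numbered arrays correlated at 0.05, -0.29 and 0.00, no array correlated best with its own number among the controls, and the block moved no count by over 1.5 times. The 7 lists past the threshold became 12 with every probe set as its own feature, 0 with an estimated correlation and 1 with fry in one direction, and 6 to 9 under the other settings. Fry in either direction, which does not compare a list with other genes, passed 9, among them the T cell, myeloid, xenobiotic, goblet, Wnt, actin and YAP lists. Median and test differed in sign for the actin list (-0.02, camera up), the interferon list (-0.01, up) and the tuft list (0.13, down, mean -0.33). No named gene or called list reversed under any setting. Among the 35 named called genes, 13 to 30 still passed when 1 array was left out, 10 passed in all 6 such fits, and 8 passed without a filter. Of 41 named genes that did not pass, 18 had a log2 change that moved by over 1.5 times when 1 array was left out. In 73 lower and 2 higher calls 1 group lay at or below the level 5 on all arrays, so their size is bounded by signal near the floor.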

Other observations

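The genes in these paragraphs were chosen after their values were seen. The prediction for the clock genes was written before the values of the 10 genes tested were examined, and its comparison across arrays was added after the result across genes was seen.

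Of 4 T cell receptor variable segments tested, 4 passed, all lower in the deficient arrays. Trgv1 and Trgv4, gamma chain segments, fell at least 4.40-fold and at least 12.2-fold, with 0 and 2 deficient arrays above 5 (limma adjusted p = 0.0046 and 0.018). Trbv1, a beta chain segment, changed by -3.04 ± 0.35 (SE) on the log2 scale and Trav9d-3, an alpha chain segment, by -2.48 ± 0.25 (adjusted p = 0.0069 and 0.0042). Probe sets of such related segments can share transcripts. Gzmb, a cytotoxic granule protease, changed by -3.38 and passed (adjusted p = 0.031), while Gzma changed by -2.99 and did not (adjusted p = 0.051). The 151 lower genes outside every fixed list include the 4 receptor segments, Cd244a and Cd160. They also include further leukocyte genes, such as Ikzf3, Sash3 and Cd69, which fell at least 8.79-fold, 7.63-fold and 7.07-fold. Of the others, 3 picked as single examples are Ugt2b5, which fell 9.49-fold (adjusted p = 0.0052), Hsd17b13, 3.17-fold (adjusted p = 0.012), and Cubn, the intestinal and renal vitamin B12 receptor, 2.38-fold (adjusted p = 0.024). These 3 do not represent the 151. Ripk3, a kinase of necroptosis, was at 2.51 with an adjusted p of 0.071.

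Nr1d1, a repressor of the circadian clock, and Usp2, a clock-driven gene, had fitted log2 changes of -2.52 and -2.17 (limma adjusted p = 0.037 and 0.030), with Nr1d1 above 5 on 2 deficient arrays. A candidate explanation is a different clock phase at isolation. It predicts that 5 other genes peaking with Nr1d1 (mean change -0.91, with Dbp at -2.33 and Per1 at -1.22) and 5 opposed genes (mean change 0.26, with Arntl at 0.76) move apart. They did across genes, by 1.18 (exact two-sided permutation p = 0.016), although genes are not independent replicates and no single gene of the 10 passed. Single genes were uneven, with Nr1d2 and Per2 of the first group at -0.38 and -0.02 and the opposed gene Nfil3 at -0.29. Across arrays the contrast did not separate the groups. Relative to the control mean it was -1.94, 1.55 and 0.40 in controls and -0.91, -1.16 and -1.46 in deficient replicates 1 to 3 (exact two-sided permutation p = 0.4). The spread among controls leaves the hypothesis open, and the time of day of isolation is not given in the sources used here.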
